A study of Rattus norvegicus with 5 samples.

How the data were processed

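Total RNA of rat retinal Müller cells was measured on 5 Affymetrix RG_U34A arrays, a chip type given per the file headers. Per the labels, 3 arrays carried cells of normal rats, each from a pool of 12, with replicates 2 and 3 described as biological replicates. The remaining 2 carried cells of rats diabetic for 6 months, also from pooled retinas of 12 rats, and the second was described as a technical replicate, so the 2 were averaged on the log2 scale into 1 pool. The deposited values are a linear intensity per probe set and array, none below 0; the summary algorithm, software and scaling that the authors used are not given in the sources used here. The arrays had not been brought to a common scale, since their 2% trimmed means ran from 73.83 to 259.7, a ratio of 3.52. The deposited experiment record of each array served only to place arrays into processing days and chip lots; the record of diabetic array 1 was nearly empty.

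The test, gene lists, rule for named genes and alternative settings were set before the data were examined. Under that plan unequal trimmed means called for quantile normalisation between arrays; values were then floored at the 20th percentile or at 20 where that was higher (the floor was 20) and converted to log2. The 59 control probe sets were left out after normalisation, and the 30% of probe sets with the lowest mean of the group means were dropped, which left 6118 of 8740. Folds are ratios on this floored log2 scale and understate changes of dim genes, and a fold against a group at the floor on all arrays is a lower bound. Because quantile normalisation gives equal ranks equal values, a probe set can have no spread between arrays. Scanner cell intensities were not used here.

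Gene symbols came from the platform annotation supplied with the values, matched through Entrez gene IDs to a RefSeq gene table of rat assembly GRCr8 for names only; 6985 probe sets matched and 0 symbols changed. Of the 8740 probe sets 7006 had 1 symbol, 308 several and 1426 none, and those with several or none were not named. A gene was represented by its brightest tested probe set with 1 symbol. Of 1030 genes with more than 1 tested probe set, 448 had probe sets that differed in sign. No coordinates are given because no genome build is named.

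The diabetic pool was compared with the 3 normal pools in limma 3.58.1 under R 4.3.3, with lmFit and eBayes (trend) and Benjamini-Hochberg adjustment over all tested probe sets, two-sided, at an adjusted p of 0.05. The fit had 2 residual and 3.54 prior degrees of freedom, all spread came from the normal pools, and the lone diabetic pool was assumed to vary like them. Fixed lists with at least 5 measured genes (20 of 21) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. With that preset its p-values reflect the spread between genes, not between pools. With an estimated correlation 0 of the 8 camera calls held, and fry, which asks whether a list's genes move on balance one way, called 0 lists. The lists covered acute-phase proteins, complement, Müller cell markers, reactive glia, photoreceptors, inner retinal neurons, endothelial cells and pericytes, leukocytes, erythrocytes, pigment epithelium, crystallins, immediate early and heat shock genes, glycolysis, antioxidant genes, glutamate handling, growth factors, interferon response, cholesterol synthesis, iron handling, oxidative phosphorylation and ribosomal proteins. Named genes were the 12 highest and 12 lowest past the threshold without overlap of arrays, filled where fewer passed from those with an unadjusted p under 0.01, then the 3 genes of each list with the largest moderated statistic and 20 genes always reported where measured. As none passed, all filled genes are given as values.

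Simulated data took the means of the 6118 probe sets, with spreads drawn from limma's fitted prior, independently per probe set. The limma step was tested on them, 3 pools against 1, with 200 probe sets changed in each of 20 simulations. It recovered 17.1% of 8-fold, 2.69% of 4-fold and 0.0746% of 2-fold changes, with 1.1 false calls on average among 14.2, so a count of 0 leaves room for large changes. In simulated independent genes camera called 91% of lists of 20 genes shifted by 0.5 and 100% of those shifted by 1. It called 1.25% of unshifted lists. Some of the real lists had estimated correlations of up to 0.658, so that 1.25% does not carry over to them. Alternatives were the deposited values unscaled, scaling to a common median, 2 other floors, 2 other filters, eBayes without trend, the 5 arrays as separate samples, 2 other thresholds, camera with an estimated correlation, fry, and leaving out each array; the 3 arrays with a low actin ratio alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9.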

Results

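Müller cells, the principal glia of the retina, were isolated from male Sprague-Dawley rats, and their total RNA was hybridised to 5 rat oligonucleotide arrays. The normal group comprised 3 pools of cells on 1 array each, with the retinas of 12 rats in each pool. The diabetic group comprised 2 arrays of cells pooled from 12 rats. The second is described as a technical replicate, so both were treated as 1 pool, but whether they carried the same RNA is not stated. Those rats had been diabetic for 6 months after streptozotocin, a toxin that destroys the insulin-producing cells of the pancreas, and received a little insulin against wasting. The question was which Müller cell transcripts differ after prolonged diabetes. The median deposited signal per array lay between 27.9 and 91.3 over 8799 probe sets, and 6118 probe sets were bright enough to be tested. The number of arrays limits the precision of every value below.

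The arrays did not separate by group alone. Over the tested probe sets, which are not independent of one another, the 2 diabetic arrays correlated at r = 0.932 and normal arrays 2 and 3, described as biological replicates, at r = 0.939. Differences over 2-fold were found for 619 and 550 probe sets in these pairs, so the technical repeat was no closer than 2 normal pools. Normal array 1 correlated with the other normal arrays at only 0.888 and 0.88, below its r of 0.907 with diabetic array 2. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 2.61 on normal array 1 and 2.55 on diabetic array 2, against 1.46 to 1.76 on the remaining 3 arrays. The same ratio for GAPDH did not show this split. It was 1.16 on normal array 1 and 1.35 on diabetic array 2, against 1.03 to 1.24 on the remaining 3. Normal array 3 and diabetic array 2 were processed on the same day with chips of 1 lot. Normal arrays 1 and 2 each had a day and lot of their own, and the record of diabetic array 1 gave none.

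The complement regulator Serping1, Spp1 and Nos2 had the largest differences among the genes named by the rule, all above normal in the diabetic pool. Serping1, which encodes the C1 inhibitor of the complement cascade, was at 10.2 times its normal signal, with a log2 difference of 3.35 (SE 0.42, 3 normal pools and 1 diabetic pool). Spp1, encoding the secreted phosphoprotein osteopontin, was at 8.89 times normal (log2 difference 3.15, SE 0.62), and Nos2, the inducible nitric oxide synthase, at 7.11 times normal (2.83, SE 0.48). That is the value of the brightest probe set of Nos2, with normal arrays at 4.60 to 5.03, near the floor of 4.32, while 2 other tested probe sets of Nos2 differed by only 0.19 (SE 1.03) and 0.028 (SE 0.49). Complement, interferon-related, acute-phase, reactive glial, iron-handling, leukocyte and photoreceptor gene lists rose as groups, whereas immediate early genes fell as a group, under a test that presets the correlation between genes. All 8 calls were lost with an estimated correlation (adjusted p = 0.361 to 0.683 with an estimated correlation, limma's camera). For complement, iron-handling, leukocyte and reactive glial genes the estimate was below the preset 0.01 (-0.049, -0.054, -0.006 and -0.004). A higher correlation between genes therefore does not account for the loss of those calls. With an estimated correlation camera uses the fit's 2 residual degrees of freedom, so that version is limited by the few pools. For the other called lists the estimate was 0.046 to 0.658. No single probe set passed limma's test after adjustment for all probe sets.

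Of the genes with an unadjusted p under 0.01 and no overlap between arrays, counting each gene by its brightest probe set, the 12 with the largest differences all lay above normal. The only qualifying probe set below normal was X03347cds_g_at of Fos, which is not the brightest of that gene. The chemokine Cxcl13 was at 6.67 times its normal signal (log2 difference 2.74, SE 0.52), and 1 of its 3 normal arrays was at the floor. The protease inhibitor Serpina3n was at 5.31 times (2.41, SE 0.35), Lcn2, encoding a lipocalin that binds bacterial siderophores, at 4.71 times (2.24, SE 0.53), and the complement protease C1s at 4.33 times normal (2.12, SE 0.43). The transcription factor Cebpd stood at 3.88 times normal (1.96, SE 0.33), the neuropeptide somatostatin, Sst, at 3.84 times (1.94, SE 0.48, with 1 normal array at the floor), and the interferon-inducible membrane protein Ifitm3 at 3.71 times (1.89, SE 0.29). Ceruloplasmin, Cp, a copper-carrying ferroxidase, was at 3.22 times normal (1.69, SE 0.30). Ddah1, whose enzyme breaks down an endogenous inhibitor of nitric oxide synthases, was at 2.9 times normal (1.54, SE 0.31). With the higher floor the difference of Sst was 1.25. Other tested probe sets of 3 of these genes differed by less, at 1.40 and 0.21 for Cebpd, 0.67 and 0.36 for Cp and -0.39 for Ddah1. Between the 2 arrays that shared a day and lot, the log2 differences of these genes were 3.00 for Serping1, 3.47 for Spp1, 2.50 for Nos2, 2.94 for Cxcl13, 2.63 for Serpina3n, 2.26 for Lcn2 and 2.03 for C1s. They were 2.38 for Cebpd, 2.24 for Sst, 1.89 for Ifitm3, 1.91 for Cp and 1.94 for Ddah1.

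**Figure D1:**
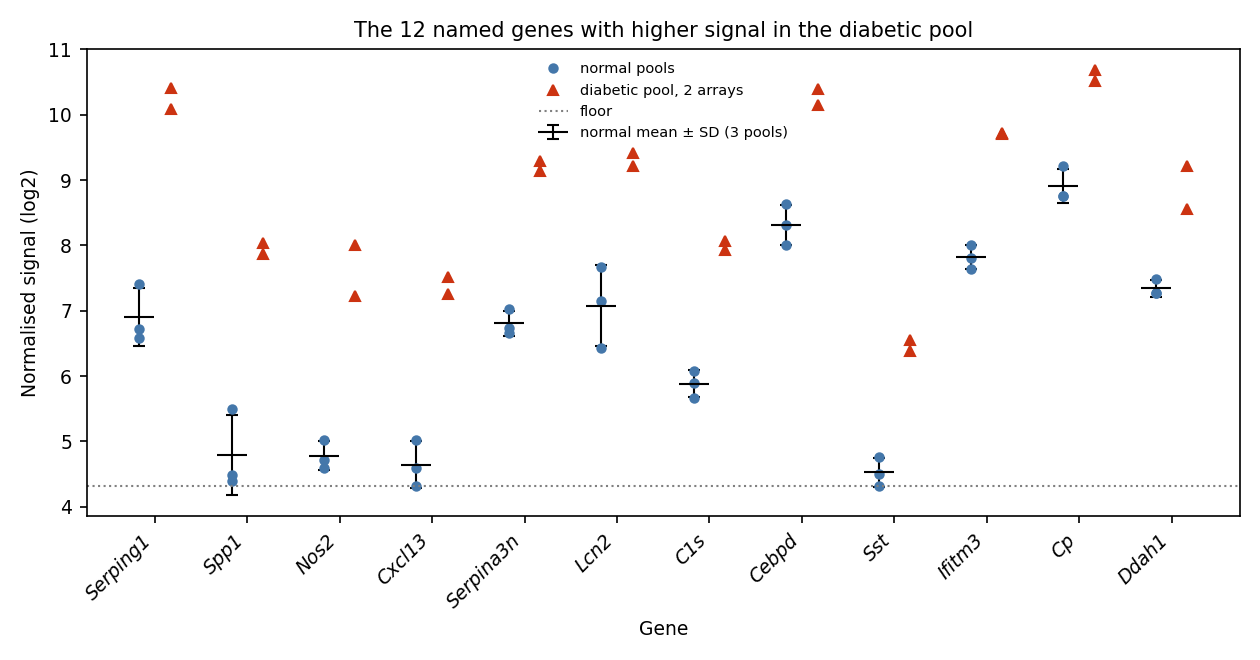
Normalised signal (log2, vertical axis) of the 12 named genes with the largest differences above normal (horizontal axis). Circles are the 3 normal pools with their mean and SD, triangles the 2 arrays of the diabetic pool, and the dotted line the floor of 20; for Serping1 the diabetic arrays read 10.09 and 10.41 against 6.58 to 7.40 in the normal pools.

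With limma, 0 of 6118 probe sets had an adjusted p under 0.05, and the lowest adjusted p was 0.495. At an unadjusted p under 0.05 there were 98 probe sets, 73 above and 25 below normal, where chance alone would give 305.9. At an unadjusted p under 0.01 there were 22, of which 21 lay above normal. The diabetic value was a mean of 2 arrays, but its spread was taken from single normal arrays. Averaging lowers array noise, so the p-values can be too high, and these 2 counts cannot be read as below chance. Both counts and the balance of directions depended on the scaling, the floor and single arrays. At an unadjusted p under 0.05 there were 34 unscaled (34 above, 0 below), 63 with median scaling (56 above, 7 below), 221 with the higher floor (187 above, 34 below) and 246 with the 5 arrays as separate samples (168 above, 78 below). There were 316 without normal array 1 (169 above, 147 below), 209 without diabetic array 1 (89 above, 120 below), 219 without diabetic array 2 (114 above, 105 below) and 507 on the 3 arrays with a low actin ratio (250 above, 257 below). At an unadjusted p under 0.01 there were 8 unscaled, 20 with median scaling, 79 with the higher floor, 75 with the 5 arrays as separate samples and 46 on the 3 arrays with a low actin ratio. There were 35 without normal array 1, 11 without normal array 3, 42 without diabetic array 1 and 42 without diabetic array 2. No other tool was run on single probe sets. Counting the diabetic arrays as separate samples, which treats the technical repeat as independent, limma called 13 probe sets, all above normal. Of these, 9 have 1 symbol, namely those of Serping1, Spp1, Nos2, Cxcl13, Serpina3n, Cebpd, Ifitm3 and Cp and rc_AA925248_at of the sodium channel gene Scn7a. The last was at least 12.8-fold higher, with all 3 normal arrays at the floor, while the brighter probe set of Scn7a differed by 0.44 (SE 0.67). Both diabetic arrays lay above all normal arrays for 583 probe sets (9.53%) and below them for 429 (7.01%). A pool with no difference and perfectly repeated arrays would give 25% in each direction. The diabetic arrays were not perfectly repeated, which lowers that share, so these counts cannot be read as below chance. The p-values rest on the spread between the 3 normal pools, which the labels call biological replicates, and assume that diabetic pools vary alike. In an exact permutation of 1 pool against 3 the smallest possible p is 0.25.

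Among unnamed probe sets, U42719_at, which is listed with 2 gene symbols, was at 13.4 times its normal signal (log2 difference 3.74, SE 0.47). The probe set with the lowest p, AF028784mRNA#1_s_at, has no symbol in the annotation used and was at 4.45 times normal (2.15, SE 0.24). Neither passed limma's adjustment over all probe sets (adjusted p = 0.495 for both).

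Complement genes rose as a list, by a mean log2 difference of 0.92 ± 1.08 (SD over 12 genes) and a median of 0.51 (camera of limma, adjusted p = 7.35e-07). With an estimated correlation the call was lost (adjusted p = 0.361 with an estimated correlation). Of the 12 genes, 10 lay above and 2 below normal, 0 passed over all probe sets, and 2, Serping1 and C1s, passed when adjusted over the list alone. C1r, the partner protease of C1s, had a log2 difference of 1.39 (SE 0.46), and the central component C3 1.68 (SE 0.73) or 1.87 (SE 0.36) on its 2 probe sets. The list's mean was 0.90 between the arrays of the shared day. For this and the other lists, camera's p-value at the preset correlation reflects the spread between genes. It does not measure the spread between pools, and there was 1 diabetic pool.

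Genes of the interferon response and antigen presentation also rose as a list, by a mean of 0.51 ± 0.53 (SD over 18 genes; limma's camera, adjusted p = 4.09e-06; adjusted p = 0.361 with an estimated correlation). Of its genes 16 lay above and 2 below normal, and 1, Ifitm3, passed when adjusted over the list alone. B2m, the light chain of class I histocompatibility molecules, had a log2 difference of 0.74 (SE 0.27) and the class I gene RT1-CE16 0.61 (SE 0.27, or 0.37 without diabetic array 2). The mean between the arrays of the shared day was 0.59.

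The acute-phase list rose by a mean of 0.35 ± 0.97 (SD over 26 genes) with a median of only 0.09 (limma's camera, adjusted p = 6.35e-04; adjusted p = 0.626 with an estimated correlation). This class is known to have been the subject of the published study of these samples, so its direction is not independent evidence. Of its genes 16 lay above and 10 below normal, and 5 passed when adjusted over the list alone, namely Serpina3n, Cebpd, Cp, Lcn2 and A2m. A2m, the protease inhibitor alpha-2-macroglobulin, had a log2 difference of 0.91 (SE 0.22), but its brightest probe set held the same normalised value on all 3 normal arrays, and its 6 probe sets ranged from -0.14 to 0.996. Ttr, the thyroid hormone carrier transthyretin, differed by 1.36 (SE 0.62) and the metalloproteinase inhibitor Timp1 by 0.69 (SE 0.33). The list's mean became 0.77 with the dimmest 50% of probe sets left out. Its call was lost without normal array 3 (adjusted p = 0.0563, within a range of 8.25e-09 to 0.84 over the alternatives), and normal pool 1 against the other normal pools gave a mean of 0.36.

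Genes of reactive glia rose by a mean of 0.41 ± 0.96 (SD over 34 genes; limma's camera, adjusted p = 6.35e-04; adjusted p = 0.361 with an estimated correlation). Of these, 22 lay above and 12 below normal, and 3, Serpina3n, Cebpd and Cp, passed when adjusted over the list alone; 7 genes of the list are also on the acute-phase list. The intermediate filament gene Vim differed by -0.10 (SE 0.28), with -0.33 without diabetic array 1 and 0.14 without diabetic array 2. Gfap was not measured by a tested probe set with 1 symbol. The call was lost without normal array 3 (adjusted p = 0.0619) and without diabetic array 1 (adjusted p = 0.0883), within a range of 2.76e-05 to 0.601 over the alternatives. The iron-handling list rose by a mean of 0.49 ± 0.87 (SD over 9 genes; limma's camera, adjusted p = 0.00351; adjusted p = 0.366 with an estimated correlation), with 6 genes above normal and Cp and Lcn2 past the threshold when adjusted over the list alone. Cp and Lcn2 are also on the acute-phase and reactive glia lists, so these calls share genes and are not separate evidence. The iron-handling list had a median of only 0.19, and its gene Hmox1, the stress-induced haem oxygenase, differed by 0.36 (SE 0.32). That list's call was lost without normal array 1 (adjusted p = 0.106), with the deposited values unscaled (0.0671), without the filter on dim probe sets (0.051) and on the 3 arrays with a low actin ratio (0.0664), within a range of 0.00158 to 0.601.

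Markers of microglia and other leukocytes, which a preparation of retinal cells can contain, rose by a mean of 0.33 ± 0.54 (SD over 24 genes; limma's camera, adjusted p = 0.014; adjusted p = 0.366 with an estimated correlation). Of these 17 lay above and 7 below normal, and 0 passed when adjusted over the list alone by limma, with 1 at an unadjusted p under 0.05. Coro1a, an actin-binding protein of leukocytes, differed by 1.43 (SE 0.51, or 0.74 with the higher floor and 0.98 unscaled) with 2 of 3 normal arrays at the floor, the microglial gene Aif1 by 0.93 (SE 0.58) and the lysosomal protease Ctss by 0.43 (SE 0.26, or 0.25 on the 3 arrays with a low actin ratio). The call was lost without normal array 3 (adjusted p = 0.143), without diabetic array 2 (0.163), with the dimmest 50% left out (0.0722) and on the 3 arrays with a low actin ratio (0.174, mean 0.19), within a range of 0.00599 to 0.601.

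Photoreceptor genes rose by a mean of 0.51 ± 0.49 (SD over 14 genes; limma's camera, adjusted p = 1.5e-04; adjusted p = 0.683 with an estimated correlation). Of these 12 lay above and 2 below normal, with 0 past the threshold when adjusted over the list alone by limma and 1 at an unadjusted p under 0.05. The short-wave opsin gene Opn1sw differed by 1.35 (SE 0.45), the arrestin gene Sag by 1.12 (SE 0.59, or 0.68 without normal array 3) and the channel gene Cnga1 by 0.91 (SE 0.47, or 0.49 without diabetic array 2). Normal pools differed among themselves by as much, since pool 1 lay 0.56 above and pool 3 lay -0.76 from the mean of the other normal pools. The list's mean was 1.02 within the shared day and 0.26 without normal array 3, and its call was lost without the filter on dim probe sets (adjusted p = 0.051, within a range of 2.23e-05 to 0.874).

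Immediate early and heat shock genes, which respond within minutes to handling or stress, fell by a mean of 0.25 on the log2 scale (SD 0.36 over 30 genes; limma's camera, adjusted p = 6.35e-04; adjusted p = 0.683 with an estimated correlation). Of these 24 lay below and 6 above normal, with 0 past the threshold when adjusted over the list alone by limma and 0 at an unadjusted p under 0.05. Klf4 differed by -1.14 (SE 0.55, or -0.74 without normal array 2), Dusp1 by -0.84 (SE 0.42, or -0.55 without normal array 2) and Fos by -0.65 (SE 0.31) on its brightest probe set, or by -1.34 (SE 0.31) on another. Normal pool 1 lay -0.56 and normal pool 2 lay 0.64 from the other normal pools. The mean was -0.04 without normal array 2 (adjusted p = 0.196), -0.44 without normal array 1 and -0.17 without diabetic array 2 (adjusted p = 0.153), within a range of 2.57e-05 to 0.874.

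**Figure D2:**
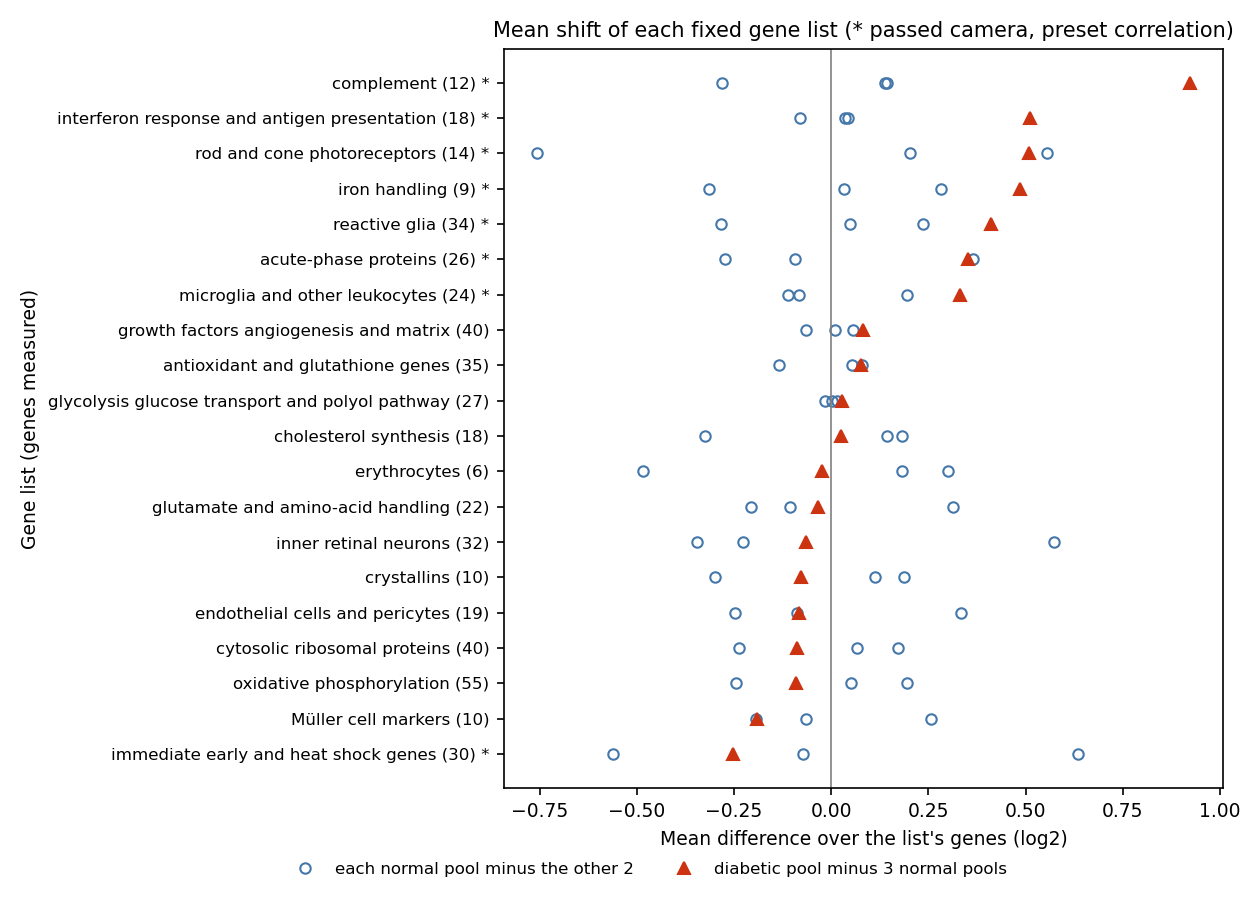
Mean log2 difference over the measured genes (horizontal axis) of each of 20 fixed gene lists (vertical axis, number of genes in brackets, asterisk for an adjusted p under 0.05 with camera's preset correlation). Triangles are the diabetic pool, averaged over its arrays, minus the 3 normal pools. Circles are each normal pool, a single array, minus the other normal pools. The complement triangle at 0.92 lies beyond its circles at -0.28 to 0.14. The photoreceptor triangle at 0.51 lies within its circles at -0.76 to 0.56.

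Müller cell markers did not pass as a list (mean -0.19 ± 0.32, SD over 10 genes; limma's camera, adjusted p = 0.0577), but did without normal array 1 (mean -0.26, adjusted p = 0.0499, within a range of 0.0499 to 0.874 over the alternatives). The mean was -0.10 without normal array 3 and -0.12 without diabetic array 2. The glutamine synthetase gene Glul differed by -0.21 (SE 0.33; -0.37 without normal array 1 and -0.046 without normal array 3), the glutamate transporter gene Slc1a3 by 0.16 (SE 0.26, or 0.08 without diabetic array 2) and the carbonic anhydrase gene Car2 by -0.34 (SE 0.27, or -0.22 without diabetic array 1). The transcriptional repressor gene Hes1 differed by -0.82 (SE 0.23) with both diabetic arrays below all normal arrays. The water channel gene Aqp4 differed by -0.48 (SE 0.39) and the potassium channel gene Kcnj10 by -0.25 (SE 0.55), but both lay above normal without diabetic array 2, at 0.17 and 0.38. Rlbp1 was not measured by a tested probe set with 1 symbol.

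The other lists that did not pass had means between -0.09 and 0.08. The mean was -0.09 for oxidative phosphorylation (55 genes; limma's camera, adjusted p = 0.0577), where Ndufv2 differed by -0.65 (SE 0.25), and -0.09 for cytosolic ribosomal proteins (40 genes, adjusted p = 0.0952), where Rps24 differed by -0.41 (SE 0.34, or -0.22 without diabetic array 2). It was 0.08 for antioxidant and glutathione genes (35 genes, 0.115), where Prdx3 differed by -0.62 (SE 0.27), and -0.08 for endothelial cells and pericytes (19 genes, 0.438), where Pdgfrb differed by -0.87 (SE 0.45), but by -1.63 without diabetic array 1 and -0.11 without diabetic array 2. Inner retinal neuron genes had a mean of -0.07 (32 genes, 0.905), with the neuropeptide gene Npy at -1.95 (SE 0.63, or -1.28 with the higher floor, 1 diabetic array at the floor) opposite to Sst. The mean was -0.08 for crystallins (10 genes, 0.787), where Crybb1 differed by -1.15 (SE 0.64, or -0.43 with the higher floor) with 1 diabetic array at the floor, and 0.03 for cholesterol synthesis (18 genes, 0.947), where Insig1 differed by 0.45 (SE 0.29, or 0.28 without diabetic array 1). For 4 lists the mean, the median and camera's direction were not all of 1 sign. These were glycolysis, glucose transport and polyol pathway genes (27 genes, mean 0.03, median -0.03, adjusted p = 0.905), growth factors, angiogenesis and matrix (40 genes, 0.08, -0.05, 0.869), glutamate and amino-acid handling (22 genes, -0.03, 0.00, 0.787) and erythrocyte genes (6 genes, -0.02, 0.08, 0.96). In these lists Hk2, a hexokinase gene, differed by 0.80 (SE 0.31, or 0.47 without diabetic array 2), Akr1b1, the aldose reductase of the polyol pathway, by 0.17 (SE 0.25), Vegfa by -0.91 (SE 0.47, or -0.53 without diabetic array 2), Slc7a1 by -0.93 (SE 0.46, or -0.18 with the higher floor and -0.61 without a floor) and Hbb by 0.17 (SE 0.51). The 4 probe sets of Vegfa ranged from -1.35 to 0.21. Of the pigment epithelium list 2 genes were measured, Ttr and Slc16a8 (0.42, SE 0.50; 0.74 without diabetic array 1 and 0.095 without diabetic array 2), too few for a test. Of the lists that did not pass, 4 in this group did when arrays were left out, with limma's camera at its preset correlation. An estimated correlation was not run with arrays left out. With all arrays it gave a camera adjusted p of 0.863 for oxidative phosphorylation, ribosomal protein and crystallin genes and 0.683 for antioxidant genes. Oxidative phosphorylation genes fell without normal array 1 (mean -0.17, adjusted p = 0.00106), without diabetic array 1 (mean -0.18, 0.00235) and with the higher floor (0.0491), within a range of 0.00106 to 0.899. Their mean was -0.027 without normal array 2 and -0.005 without diabetic array 2. Ribosomal protein genes fell without normal array 1 (mean -0.17, adjusted p = 0.00387), without diabetic array 2 (mean -0.19, 0.00562) and on the 3 arrays with a low actin ratio (0.000774), within a range of 0.000774 to 0.874, with a mean of 0.015 without diabetic array 1. Antioxidant genes rose without diabetic array 2 (mean 0.20, adjusted p = 0.0132) and on the 3 arrays with a low actin ratio (0.00879), within a range of 0.00879 to 0.995, with a mean of -0.039 without diabetic array 1. Crystallins fell without diabetic array 1 (mean -0.32, adjusted p = 0.0355, within a range of 0.0355 to 0.978), with a mean of 0.17 without diabetic array 2.

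Each normal pool was also set against the other normal pools. It then had more probe sets at an unadjusted p under 0.05 (limma) than the diabetic pool against those same pools. Each normal pool was a single array, whereas the diabetic pool was the average of both its arrays. Averaging lowers array noise and can by itself give fewer small p-values. That count therefore cannot decide whether the diabetic pool stood further apart than a normal pool. Camera also called lists for every normal pool set against the other normal pools, 5 for pool 1, 4 for pool 2 and 1 for pool 3. Among those lists were acute-phase, photoreceptor, immediate early and oxidative phosphorylation genes, but neither complement genes (adjusted p = 0.515 to 0.804 with limma's camera) nor interferon-related genes (adjusted p = 0.442 to 0.85).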

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

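The fit on only the 3 arrays with a low actin ratio was chosen after seeing the data; the other alternatives were planned. The count of 0 probe sets held with limma under every scaling, both floors, the stricter filter, eBayes without trend and an adjusted p of 0.10, and was 0 to 0 when each array was left out in turn. The separate number at an unadjusted p under 0.05, 98 as reported, was 34 unscaled, 63 with median scaling, 221 with the higher floor and 72 to 316 when arrays were left out. The count of 0 became 170 without the filter on dim probe sets; 162 of these had all 3 normal arrays at the floor and so no spread, which the floor itself produces. The same count was 13 with the 5 arrays as separate samples, where the technical repeat adds a degree of freedom, and 22 at an unadjusted p under 0.01 with a 1.5-fold difference and no overlap, a looser threshold by construction. The count of 8 called lists became 0 with an estimated correlation and 0 with fry, and ranged from 5 to 10 when arrays were left out, with the 5 found without normal array 3. Without scaling, the median of all probe sets shifted by 0.47, and values are relative to it. Complement and interferon genes kept their calls in 14 of 16 alternatives, the exceptions being the estimated correlation and fry. Of uncalled values, the erythrocyte mean turned to 0.001 without a floor and 0.082 with the higher floor, the glutamate-handling mean to 0.013 with the higher floor and 0.038 with the dimmest 50% out, and the inner retinal mean to 0.01 with the dimmest 50% out; the cause was not tested. On the 3 arrays with a low actin ratio, values turned for Slc16a8 (-0.06), Vim (0.12), Kcnj10 (0.39), Cryaa (0.49), Fasn (0.19), Lss (0.029) and the means of endothelial (0.048), crystallin (0.23), glycolysis (-0.049) and cholesterol genes (-0.013); the cause was not tested. Leaving out arrays gave ranges across 0 for Hbb (-0.12 to 0.51), Vim (-0.33 to 0.14), Rpl35a (-0.73 to 0.066), Dlat (-2.04 to 0.45), Slc1a2 (-2.29 to 0.083), Kcnj10 (-0.88 to 0.38), Cryaa (-0.96 to 0.36), Lss (-0.83 to 0.057), Bcat1 (-0.89 to 0.014), Aqp4 (-1.13 to 0.17) and Uqcrfs1 (-1.42 to 0.044). The same held for the means of endothelial (-0.16 to 0.03), erythrocyte (-0.18 to 0.083), cholesterol (-0.082 to 0.095), inner retinal (-0.18 to 0.13), glutamate-handling (-0.10 to 0.072), antioxidant (-0.039 to 0.20), ribosomal (-0.19 to 0.015), crystallin (-0.32 to 0.17) and glycolysis genes (-0.054 to 0.11); fewer arrays entered these fits. The pool or the processing day as a random block was not run, because with 1 repeated block its correlation could not be estimated, and the day as a fixed block leaves no residual degrees of freedom, so values within the shared day carry no test. No paired analysis was possible, because there was 1 diabetic pool and the labels name no pairing between normal and diabetic pools. Signal near the floor limits the values of dim genes such as Cxcl13, Sst, Coro1a, Crybb1, Npy and Slc7a1.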

Other observations

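The tests of explanations below were chosen after the results were seen. The transcriptional repressor genes Hes1 and Hes5 and the gene Nrarp, which Notch signalling is known to activate, lay below normal in the diabetic pool, with log2 differences of -0.82 (SE 0.23), -0.83 (SE 0.27) and -1.10 (SE 0.31). Both diabetic arrays lay below all 3 normal arrays for each gene, but none passed limma's adjustment over all probe sets (adjusted p = 1 for each). Hes5 and Nrarp were chosen after their values were seen. Among other genes noticed in the same way, the galectin gene Lgals3 had a log2 difference of 2.72 (SE 1.03). The interferon-induced genes Mx1 and Mx2 had differences of 0.97 and 1.18 with both diabetic arrays above all normal arrays. Lgals3 is on the reactive glia list and Mx1 and Mx2 are on the interferon list, so they are not separate evidence.

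Complement, interferon and antigen-presentation genes stood together 0.68 above normal (30 genes). Processing day or chip lot is argued against, but only by 1 array against 1. The 2 arrays of the same day and lot differed by 0.714 (SE 0.137 over genes, not over pools). No pair of normal arrays differed by more than 0.11 on the joined lists. For complement genes alone, normal pool 1 lay -0.28 from the other normal pools, against 0.90 between the arrays of the shared day. The lists were joined after the results were seen. The 2 arrays also differed in actin ratio, at 2.55 on diabetic array 2 and 1.46 on normal array 3. A larger share of leukocytes stays open, since leukocyte markers outside the lists averaged 0.28, and the lists' other genes exceeded them by 0.394 (SE 0.193) over all arrays but by only 0.25 (SE 0.20) within the shared day. Variation between pools also stays open: the largest shift of a normal pool was -0.086, but with 4 pools the smallest share chance allows is 0.25. Diabetes, the difference the design names, may account for the pattern and was not tested apart from these.

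For photoreceptor genes, variation between pools is a possible explanation, as a normal pool lay -0.758 from the other normal pools, beyond the diabetic pool's 0.51, and differing carry-over of photoreceptor RNA could produce such shifts. The shared day stays open: the difference between its 2 arrays was 1.02 (SE 0.22), but normal arrays differed by up to 0.88, and the normal array of that day is the pool that stands apart (mean 0.26 without it). An effect of diabetes on photoreceptor RNA in these preparations remains untested.

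For Hes1, Hes5 and Nrarp, a lower share of Müller cell RNA would be expected to lower the other 9 Müller cell markers as well. Their mean was -0.12 (SE 0.08) against -0.92 for the 3 genes, and -0.38 (SE 0.20) against -1.27 within the shared day. Aqp4 (-1.41) and Kcnj10 (-1.33) were as low there. Because the 3 genes were picked for lying low, part of this gap is fixed by the choice. A lower share of Müller cell RNA therefore stays open. The shared day stays open, because the 3 genes were picked with both diabetic arrays below all normal arrays, which fixes the sign of their mean of -1.271 between its 2 arrays. Variation between pools cannot be excluded with 4 pools, although the largest shift of a normal pool was 0.212. Lower Notch signalling in the diabetic pool is a hypothesis that may be followed up, but 0 further Notch target genes of those looked for were measured, so it stays open.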
